A study of Mus musculus with 6 samples.

How the data were processed

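RNA sequencing libraries from 6 mouse skin samples were used, 1 for each combination of treatment (C-PC or none) and stage of wound healing (early, middle or late). Per the labels' protocols, total RNA was isolated with a column kit and made into libraries with a kit that does not mark the strand. The aligner, the counting tool and the annotation release are not given in the sources used here. The only genome build that the submitters' processing notes name is hg38, a human build, while the gene identifiers and coordinates in the tables are of mouse. Of 26644 genes listed in any table, 26632 have an identifier in GENCODE release M21 (GRCm38) and 25885 (97.2%) the same coordinates, so coordinates are given on GRCm38 as the tables hold them.

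The authors deposited 3 tables, 1 per stage, each with 1 value per gene for the C-PC library and for its control. Per the file headers each table also holds the authors' log2 fold change, p-value and adjusted p-value. The deposited values are a signal, read counts scaled by the authors to a common library size of the 2 libraries in a table. This was worked out from the values: each is a whole multiple of 1 step per column, and 100% of the values in each library gave a whole number of reads within 0.1 read. The recovered reads per library lie between 15863637 and 18028674. Scaling these reads by the trimmed mean of M-values (TMM) gave the authors' scaling of each pair, with a largest log2 difference of -4.4e-06. Genes with fewer than 2 reads over a pair are not listed, which leaves 19360 genes in all 3 tables. The tables were scaled separately, so levels are set across stages only through recovered reads.

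The design was written for counts, with edgeR's quasi-likelihood test as the main test, before the data were examined. Since the deposited values turned out to be scaled, limma on log2 values is the main test, and edgeR on recovered reads is an added alternative. Within a stage no test was made, as each group has 1 library. The log2 ratio of the deposited values plus a pseudocount of 2 is given, with an exact 95% conditional binomial interval from the recovered reads. On this scale the change of genes with low values is understated. Genes with at least 10 reads in 1 of the 2 libraries were compared, and a gene was called apart when its ratio was at least 2-fold and its interval excluded equality. Intervals and floors cover counting error only. Where a library had 0 reads the fold was computed against 3 reads and is given as "at least". The 95% interval of such a gene reaches somewhat smaller folds, so this floor is no strict bound. CPM values within a stage are scaled to the total reads on genes, without TMM.

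The C-PC effect over the stages was fitted with limma (empirical Bayes with trend and robust settings) on log2 of the deposited values plus 2, with the stage as a block. Stages were compared on log2 CPM of the recovered reads after TMM (prior count 2) with the treatment as covariate. After edgeR's expression filter 16591 genes were tested, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment. Nothing in the labels says that libraries of a stage came from the same animal. With 1 library per treatment and stage, the error is how much the C-PC difference varies from stage to stage. That error holds both the spread between samples and any change of the effect with stage, which cannot be told apart. In comparisons of stages, it is how much the stage difference varies between treatments. The 37 gene lists were fixed before the data were examined. Within a stage a list's median was set among 10000 random lists of the same size, matched in 20 bins of expression. Over stages, camera was run with its preset correlation and with an estimated one. The named genes follow a rule set in advance: within a stage, the 10 highest and 10 lowest ratios among protein-coding genes with a mean of at least 5 CPM in the pair, leaving out symbols of the Gm and Rik kinds; in tests with no passing gene, the 5 smallest p-values in each direction; and from each list up to 4 members with the largest ratios, at the same level. Not every gene that the rule picks is named. Genes named outside this rule are marked where they appear. Overlapping and antisense genes cannot be separated in libraries without strand.

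The tests were tried on simulated counts with each gene's mean over all libraries, the real depths, 16591 genes, a dispersion of 0.1 and 200 genes changed. Apart from the changed genes, all libraries shared these means, so the simulated error held no change of the C-PC effect with stage. Over the stages limma recovered 10%, 88% and 100% of genes changed 2-fold, 4-fold and 16-fold. Between the late and early stages it recovered 0%, 68.5% and 97%. The interval rule within a stage marked 0.325% of unchanged genes under counting noise alone and 14.2% with the dispersion of 0.1, so it describes the 2 libraries and not the treatment.

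Alternatives set in advance were DESeq2 size factors and its Wald test, total-read scaling, prior counts of 0.5 and 10, other filters, a 4-fold limit, the authors' adjusted p, leaving out the 50 most abundant genes, no block or covariate, and leaving out each stage or library. edgeR's test, pseudocounts of 0.5 and 10 in the fits, genes missing from a table set to 0, and total-read scaling of the lists were added after seeing the data. Computations used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.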

Results

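Gene expression was measured by RNA sequencing in mouse skin during wound healing. The tissue was either treated with C-phycocyanin (C-PC), a blue light-harvesting protein of the cyanobacterium Spirulina, or left untreated, and it was sampled at an early, a middle and a late stage. The 6 groups of this design hold 1 library each, so no value has a replicate within its group. The early control held 18028674 reads on genes, the early C-PC library 16835495, the middle control 15863637, the middle C-PC library 17184948, the late control 16187258 and the late C-PC library 17033889. Intervals given here cover counting error only, and a difference between 2 libraries has no replicate check.

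The 6 libraries fell into 3 kinds by their most abundant transcripts. Collagen genes led both early libraries and the middle control, with Col3a1, a fibrillar collagen of skin and granulation tissue, at 17805, 19109 and 34117 CPM (counts scaled to the total reads on genes). The muscle genes Acta1, the skeletal muscle actin, and Myh4, a fast myosin heavy chain, led the middle C-PC library and the late control. Acta1 stood at 38404 CPM in the middle C-PC library and 35606 CPM in the late control. Genes of the hair follicle led the late C-PC library, where Tchh, the trichohyalin of the inner root sheath, stood at 18637 CPM. Across 15393 genes the middle C-PC library and the late control had the highest Spearman correlation of any pair, 0.980, followed by the early pair at 0.977. The middle C-PC library correlated with its own control at 0.735, and the late C-PC library with its own control at 0.658. Genes are not independent replicates, so these correlations describe the libraries and carry no p-value.

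**Figure D1:**
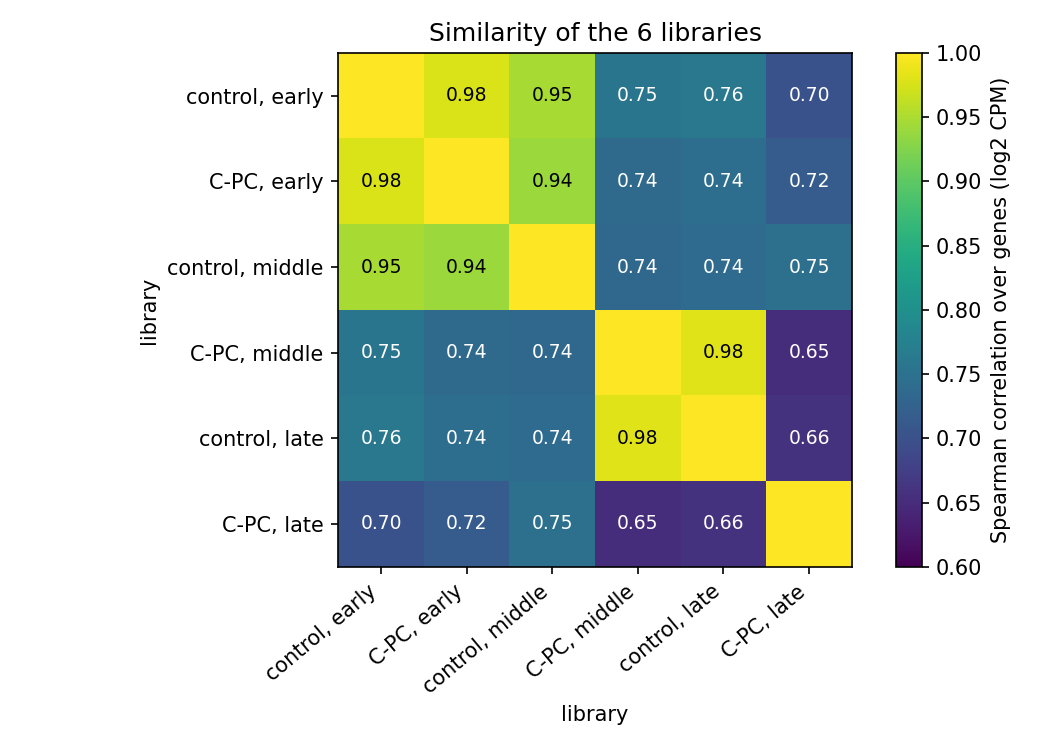
Spearman correlation of log2 CPM over 15393 genes for every pair of the 6 libraries, with the libraries on both axes and the correlation as colour and number. The middle C-PC library and the late control share a correlation of 0.980, and the late C-PC library has no correlation above 0.748.

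At the early stage, C-PC was compared with its control to ask which genes differ while inflammation and new tissue formation are under way. Genes of granulocyte precursors were lower in the C-PC library. Camp, an antimicrobial peptide of granules, stood at 0.416 CPM against 237 in the control, a log2 ratio of -8.78 (95% interval -10.45 to -8.09). Elane, the neutrophil elastase, gave -9.19 (-16.04 to -8.25), Mpo, the myeloperoxidase, -8.31 (-9.83 to -7.64) and Ngp, a neutrophil granule protein, -7.21 (-7.55 to -6.95). Ms4a3 and the eosinophil genes Prg2 and Epx had 0 reads with C-PC, which makes them at least 112-fold, 326-fold and 112-fold lower. Ibsp (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469, build GRCm38), the bone sialoprotein, had 3018 reads in the control and 0 with C-PC, at least 925-fold lower. Slc4a1, the anion exchanger of red cells, gave -7.37 (-11.39 to -6.48), and Myh7, the slow muscle myosin, -8.17 (-11.16 to -7.34).

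The Schwann cell, mast cell and myofibroblast lists had higher medians in the early C-PC library. The Schwann cell and nerve list had a median log2 ratio of 1.28, with 6 of 12 members at least 2-fold higher. Cdh19, a cadherin of the Schwann cell lineage, had 186 reads against 25 in the control (2.92, 2.41 to 3.68). The mast cell list had a median of 0.86 (4 of 9 members at least 2-fold higher), with the tryptase gene Tpsab1 at 1.97 (1.70 to 2.29) and the carboxypeptidase gene Cpa3 at 1.39 (1.16 to 1.64). The myofibroblast list had a median of 0.56 (3 of 12), with Lrrc15 at 1.45 (1.37 to 1.53) and the smooth muscle actin Acta2 at 0.93 (0.87 to 1.00). The transcription factor gene Shox2 had the highest ratio, 3.51 (3.01 to 4.29). H2-Eb1, a class II antigen-presenting gene, stood at 48.5 CPM against 5.16, whereas the class II genes H2-Ab1 and Cd74, named after their values were seen, were lower with C-PC, at 55.5 against 126 and 311 against 646 CPM. Gapdh, Rpl21, Srp54b, Cwc22 and Tpsab1 share sequence with near-identical copies or pseudogenes, so their high ratios, of 3.34, 2.23, 2.72, 2.18 and 1.97, are uncertain.

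Of the 37 gene lists, 19 had an early median outside the central 95% of 10000 random lists of like size and expression. Members of a list vary together, so a list can leave this range without any effect of treatment, and the number of such lists has no chance value here. The 12 lower ones were T and NK cells (-1.44, 11 of 15 members at least 2-fold lower), antimicrobial genes (-1.22), B and plasma cells (-1.22), skeletal muscle (-1.15, 14 of 21), erythrocytes (-0.62), neutrophils (-0.61, 7 of 18), myogenic regeneration (-0.55), adipocytes (-0.43), the TGF-beta pathway (-0.32), mitochondrially encoded genes (-0.18), endothelium (-0.12) and the insulin pathway (-0.11). In these lists the light chain gene Igkc gave -6.38 (-6.87 to -6.03), the iron-binding Lcn2 -2.24 (-2.32 to -2.16) and the fast myosin Myh2 -1.81 (-1.96 to -1.68). The other higher lists were epidermal differentiation (0.44, 5 members), wound-edge keratinocytes (0.37), the Wnt pathway (0.26) and interferon-stimulated genes (0.19). The summed levels of the wound-edge list (388 CPM with C-PC against 399) and of the erythrocyte list (962 against 897) went the other way from their medians. The wound-edge median turned to -0.02 when only members with a mean of 5 CPM or more were kept. Inside the random range lay cytokines and chemokines (-0.01), macrophages (0.12), alternatively activated macrophages (0.16), granulation tissue matrix (0.05), matrix proteases (0.05), basal keratinocytes (0.11), hair follicle (-0.49), sebaceous gland (-0.01), angiogenic factors (0.02) and pericytes (0.06). The same held for melanocytes (0.16), proliferation (-0.07), antioxidant Nrf2 targets (0.07), growth factors (-0.10), glycolysis (-0.01), oxidative phosphorylation (-0.02), immediate early genes (0.07) and sex-linked genes (-0.04). The means of the alternatively activated macrophage, matrix, protease and angiogenic lists had the other sign, and the angiogenic median turned negative under scaling by total reads.

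Of 16589 genes compared early, 1622 were at least 2-fold apart with an interval excluding equality, 485 higher and 1137 lower with C-PC. In a simulation with a negative binomial dispersion of 0.1 between libraries and no true change, the same rule marked 14.2% of genes, against 9.78% here, so the early count does not exceed what that assumed variance gives alone. The authors' deposited table holds 558 genes that pass both its adjusted p of 0.05 and 2-fold.

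At the middle stage, transcripts of epidermis, inflammation and granulation tissue were lower in the C-PC library than in its control, and those of muscle and fat were higher. The keratin genes Krt14 and Krt5 of the basal layer had 13548 and 5421 reads in the control and 0 with C-PC, at least 3354-fold and 1342-fold lower. Krt1 of the upper layers was at least 1775-fold lower. The wound-edge keratins Krt6b, Krt6a and Krt16 were at least 1288-fold, 1103-fold and 1078-fold lower, with reads of Krt6a and Krt6b open to sharing. The chemokine gene Cxcl5, which attracts neutrophils, was at least 2422-fold lower, and Serpinb2 at least 756-fold lower. Il1b gave a log2 ratio of -9.74 (-16.49 to -8.71), BC100530 -10.71 (-17.47 to -9.68) and Prss35 -10.11 (-16.86 to -9.08).

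Muscle and fat genes were among those higher in the middle C-PC library. All 21 skeletal muscle genes compared were at least 2-fold higher (median 4.51), and the list summed to 195043 CPM against 12836 in the control. Myod1, a transcription factor that sets muscle identity, stood at 72.6 CPM against 1.39 (6.11, 5.65 to 6.93). All 18 adipocyte genes were higher (median 3.80), among them Cfd, which encodes adipsin, at 6.16 (6.04 to 6.29) and Retn, which encodes resistin, at 5.54 (5.24 to 5.94). Thrsp, a regulator of lipid synthesis, gave 6.58 (6.33 to 6.89), Adrb3, the beta-3 adrenergic receptor of fat cells, 6.73 (6.01 to 9.26), Adig, an adipogenesis gene, 6.39 (5.69 to 8.56) and Cyp2e1 6.35 (6.14 to 6.60). Ces1f and Lrtm2 had 0 control reads and were at least 203-fold and 125-fold higher. Lrtm2 lies within the span of Cacna2d4, given below, and reads of overlapping genes cannot be separated without strand. Nmrk2, a muscle kinase of NAD synthesis, gave 6.89 (6.30 to 8.25), Retnla, a resistin-like gene, 7.11 (6.40 to 9.64), Cacna2d4 6.46 (5.72 to 9.56) and Klhdc7a 6.34 (5.69 to 8.07).

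Of the 37 lists, 25 lay outside the central 95% of random lists at the middle stage. The 7 higher ones were skeletal muscle, myogenic regeneration (4.18, 11 of 11), adipocytes, oxidative phosphorylation (2.51, 19 of 19), mitochondrially encoded genes (2.13), Schwann cells (1.39) and glycolysis (1.17). Among the 18 lower ones, medians are given with genes at 0 reads also set to the floor of 3 reads where that moved them. They were wound-edge keratinocytes (-6.88, at the floor -6.07), epidermal differentiation (-6.77, at the floor -6.60, 23 of 23), cytokines and chemokines (-6.14, at the floor -5.70, 18 of 20), basal keratinocytes (-4.78, at the floor -4.36), neutrophils (-4.77, 18 of 18), matrix proteases (-4.56, at the floor -4.55), T and NK cells (-4.30, at the floor -3.87), antimicrobial genes (-3.67, at the floor -3.18), granulation tissue matrix (-3.65, 24 of 24), proliferation (-3.61, 24 of 25), hair follicle (-3.47, at the floor -2.57) and macrophages (-3.47, 15 of 16). The rest were B and plasma cells (-3.07), interferon-stimulated genes (-2.26), the Wnt pathway (-1.70), alternatively activated macrophages (-1.64), myofibroblasts (-1.27) and immediate early genes (-1.24). In these lists the matrix genes Tnc and Postn gave -5.91 (-6.08 to -5.75) and -5.36 (-5.44 to -5.28), and Mki67, a marker of dividing cells, -6.04 (-6.61 to -5.64). Inside the range lay mast cells (-1.47), sebaceous gland (-1.21), melanocytes (-1.21), growth factors (-0.93), Nrf2 targets (-0.62), the TGF-beta pathway (-0.55), angiogenic factors (-0.40), erythrocytes (-0.21), pericytes (0.77), endothelium (0.35), sex-linked genes (0.15) and the insulin pathway (0.14). The endothelial, sex-linked and insulin medians turned negative when libraries were scaled by total reads, and the summed level of the sebaceous list was higher with C-PC, 8080 against 712 CPM. So was that of the myofibroblast list, 18864 against 4554 CPM, with 2 members higher and 6 lower.

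Of 17076 genes compared at the middle stage, 8836 were at least 2-fold apart, 4036 higher and 4800 lower (45.7% higher). Scaling by total reads gave 2686 higher and 6851 lower (28.2% higher), since it moved the median of all genes from -0.13 to -0.66. The authors' deposited table holds 8300 genes past its adjusted p and 2-fold.

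At the late stage, hair follicle, epidermal and pigment cell genes were higher in the C-PC library, and muscle, fat and vessel genes were lower. All 24 hair follicle genes compared were higher, with a median log2 ratio of 12.89 (at the floor 12.21), and the list summed to 61947 CPM against 1.61 in the control. Tchh (ENSMUSG00000052415, chromosome 3, 93442330 to 93449077) had 317456 reads against 1, a log2 ratio of 16.26 (15.18 to 22.96). The inner root sheath keratins Krt71, Krt25 and Krt73 had 0 control reads and were at least 41405-fold, 22460-fold and 6793-fold higher, and Krt27 gave 13.52 (12.52 to 17.42). The hair shaft genes Krtap15, Krtap8-1, Krt33a and Krt83 were at least 8345-fold, 8209-fold, 7368-fold and 6687-fold higher, and Krtap7-1 gave 13.57 (12.49 to 20.27), although reads of these families can be split between near-identical members. The pigment genes Tyrp1 and Tyr, enzymes of melanin synthesis, were at least 1292-fold and 552-fold higher, in a melanocyte list higher in 10 of 10 members (median 8.20, at the floor 7.78).

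The lower genes of the late comparison were led by muscle. All 21 skeletal muscle genes compared were lower (median -6.85), and the list summed to 2763 CPM against 189355 in the control. Myh4 gave -11.87 (-12.08 to -11.70), Myh7 -9.18 (-16.27 to -8.49), Actc1, the cardiac actin, -8.84 (-9.35 to -8.51), Mybpc2 -8.46 (-8.63 to -8.31) and Pvalb, a calcium buffer of fast fibres, -8.25 (-8.36 to -8.16). Prkag3 and Ampd1, enzymes of muscle energy balance, gave -8.74 (-9.90 to -8.22) and -8.67 (-9.07 to -8.38). The slow muscle gene Myl2 and Mettl21e had 0 reads with C-PC and were at least 408-fold and 252-fold lower. Ngp, the granule protein, was at least 449-fold lower. All 18 adipocyte genes were lower (median -2.55), with Car3, a carbonic anhydrase of fat and muscle, at -3.86 (-3.88 to -3.83).

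Of the 37 lists, 26 lay outside the central 95% of random lists at the late stage, 11 higher and 15 lower. Besides the hair follicle and melanocyte lists, the higher ones were epidermal differentiation (7.59, at the floor 7.24, 24 of 24), wound-edge keratinocytes (6.82, at the floor 5.95), basal keratinocytes (6.28), proliferation (4.41, 24 of 25), the Wnt pathway (3.11, 17 of 18), sebaceous gland (1.90, 9 of 15, 3 lower), immediate early genes (1.14), macrophages (0.94) and granulation tissue matrix (0.92, 12 of 24). The summed level of the sebaceous list went the other way, 2263 CPM with C-PC against 21584 in the control, of which Scd1 made up 1409 and 20205. Top2a, a topoisomerase of dividing cells, gave 5.84 (5.46 to 6.36), and Lef1, a Wnt transcription factor, 5.59 (5.05 to 6.44). Besides muscle and fat, the lower ones were erythrocytes (-3.30, 8 of 8), myogenic regeneration (-2.53), neutrophils (-2.29), pericytes (-2.15), B and plasma cells (-1.87), endothelium (-1.82, 14 of 16), oxidative phosphorylation (-1.81), mitochondrially encoded genes (-1.80), glycolysis (-1.40), Schwann cells (-1.30), angiogenic factors (-1.04), interferon-stimulated genes (-0.89) and growth factors (-0.78, with a mean of 0.18 and a summed level of 391 CPM against 312). Vegfa, the main growth factor of vessels, gave -3.49 (-3.67 to -3.34) and its receptor gene Kdr -2.76 (-2.89 to -2.65). Inside the range lay cytokines (1.26), mast cells (1.04), alternatively activated macrophages (0.99), antimicrobial genes (0.83), matrix proteases (0.27), T and NK cells (0.22), sex-linked genes (0.07), myofibroblasts (-0.03), Nrf2 targets (-0.08), the TGF-beta pathway (0.00 after rounding) and the insulin pathway (-0.20). The myofibroblast, Nrf2, TGF-beta and insulin medians turned positive under scaling by total reads.

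Of 17073 genes compared at the late stage, 8435 were at least 2-fold apart, 4484 higher and 3951 lower (53.2% higher). Scaling by total reads gave 6899 higher and 2654 lower (72.2% higher), since it moved the median of all genes from 0.15 to 0.69. The authors' deposited table holds 7927 genes past its adjusted p and 2-fold.

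**Figure D2:**
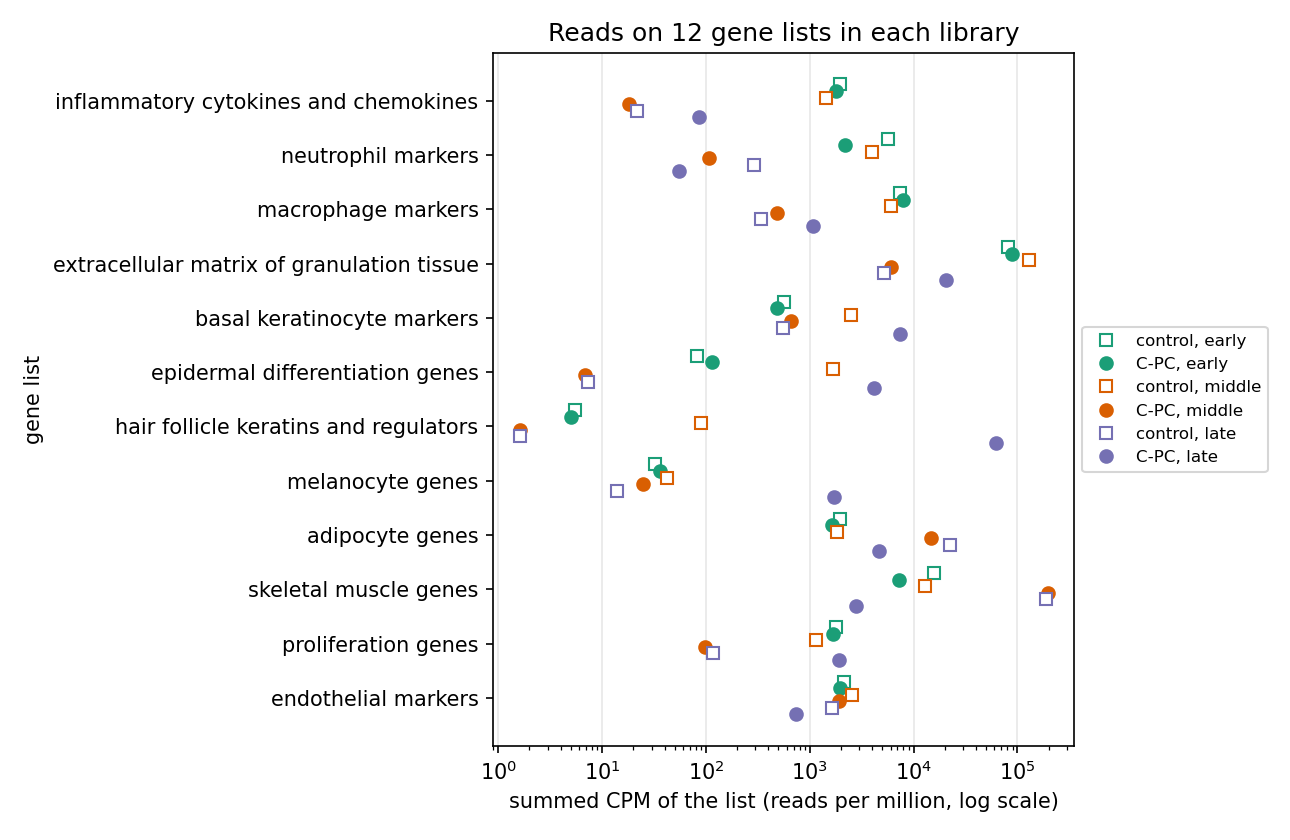
Summed CPM of the members of 12 gene lists (log axis) in each of the 6 libraries, open squares for controls and filled circles for C-PC, coloured by stage. The skeletal muscle list reaches 195043 CPM in the middle C-PC library and 189355 CPM in the late control, and the hair follicle list 61947 CPM in the late C-PC library.

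**Figure D3:**
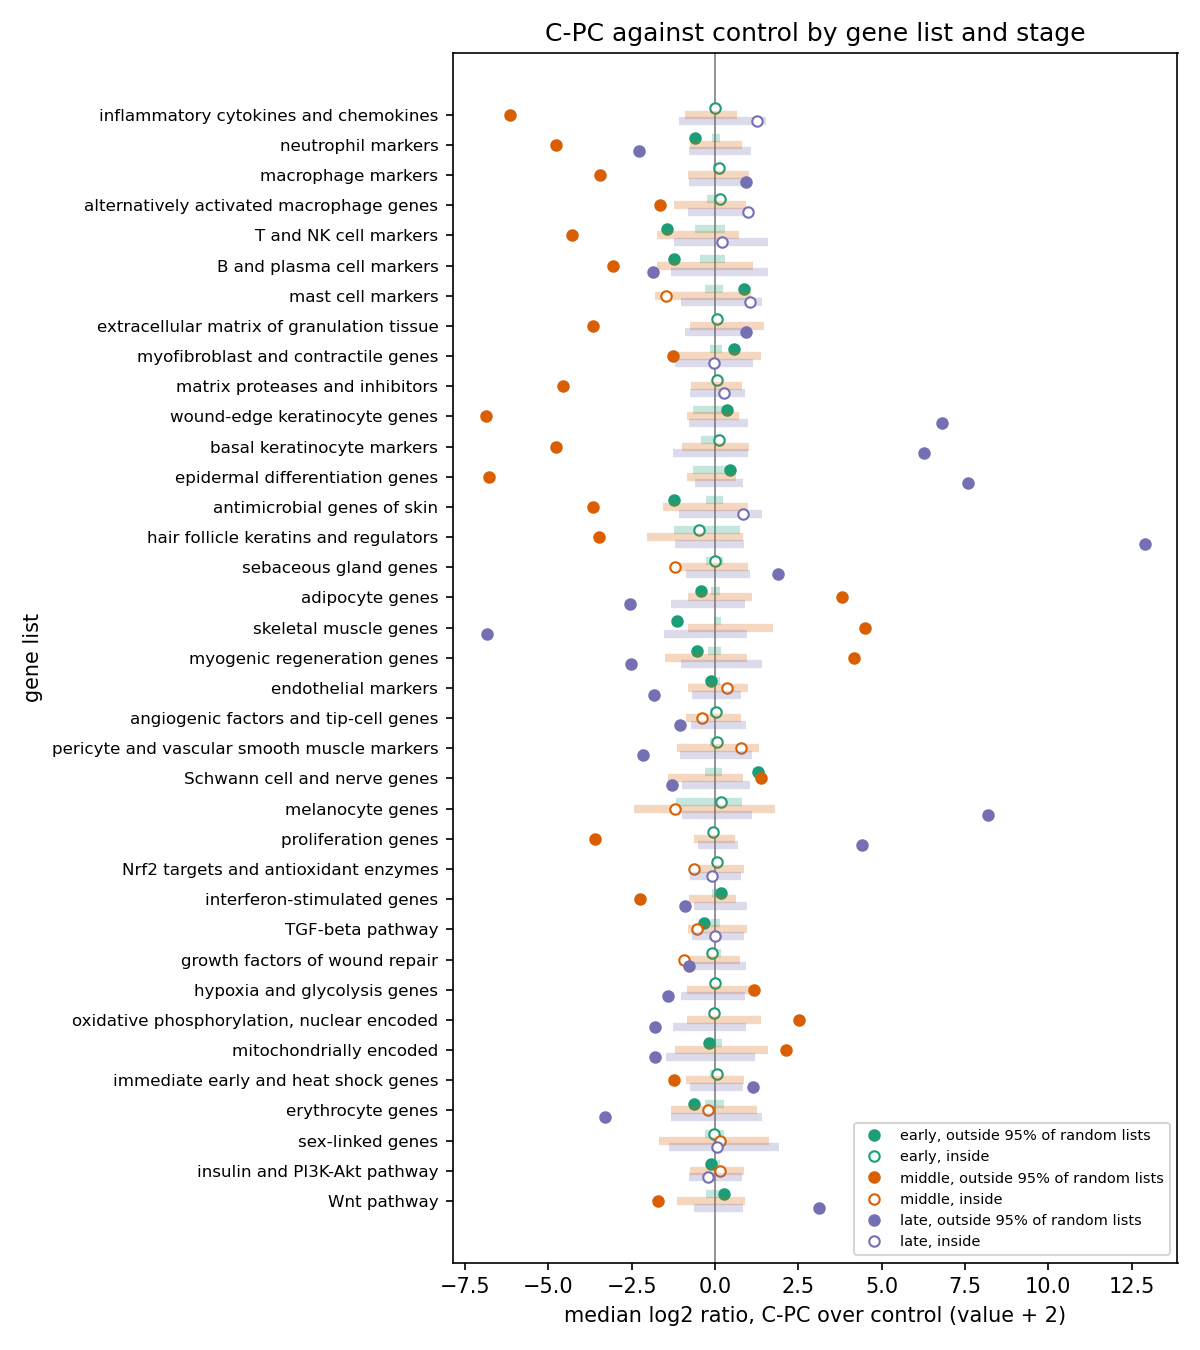
Median log2 ratio of C-PC over control for each of the 37 gene lists (vertical axis), coloured by stage, with pale bars for the central 95% of random lists and filled points outside it. Middle and late points lie on opposite sides of 0 for muscle (4.51 and -6.85) and epidermal differentiation (-6.77 and 7.59).

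The C-PC ratios of the stages were then compared with each other. Genes of muscle and fat that were higher with C-PC at the middle stage were lower at the late stage, and genes of epidermis and dividing cells went the opposite way. Over 15063 genes the middle and late log2 ratios had a Pearson correlation of -0.638 (Spearman -0.621), and 74.0% of genes had opposite signs. The early and late ratios gave 0.194 (Spearman 0.174). The early and middle ratios gave -0.022 (Spearman -0.134). These are 3 relations across genes, which are not independent replicates, and no p-value is given. The middle C-PC library and the late control were nearly alike (Spearman 0.980). Their shared profile enters the middle ratio from above and the late ratio from below. Opposite signs at these stages therefore largely restate that likeness and are no separate result on C-PC.

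**Figure D4:**
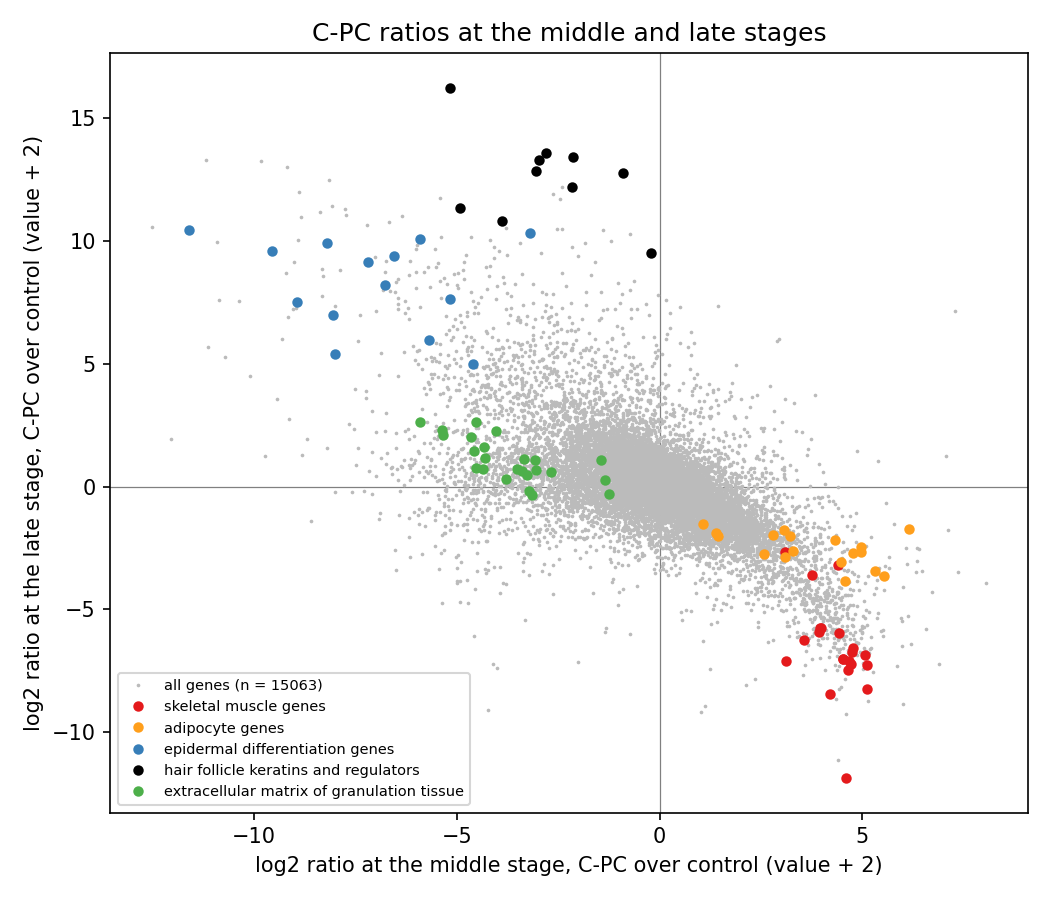
Log2 ratio of C-PC over control at the late stage (vertical axis) against that at the middle stage (horizontal axis), 1 point per gene for 15063 genes, with 5 gene lists in colour. The cloud slopes downward (Pearson -0.638), with muscle and fat genes at the lower right and epidermal and hair follicle genes at the upper left.

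The difference with C-PC that was common to the 3 stages was tested with the stage as a block, 3 libraries against 3. Granulocyte genes had the smallest p-values on the lower side but did not pass. Ltf, the lactoferrin of neutrophil granules, gave a log2 difference of -6.04 (SE 0.77) and was lower with C-PC in each of the 3 pairs. Cd177, a neutrophil surface protein, gave -4.79 (SE 0.65), Ngp -6.85 (SE 1.04) and Camp -6.73 (SE 1.09). On the higher side stood Tbx1, a transcription factor, at 3.08 (SE 0.70), Golga7b at 2.60 (SE 0.77), AK157302 at 2.26 (SE 0.75), Grik3 at 2.23 (SE 0.74) and Myh8, a perinatal myosin, at 1.79 (SE 0.60). Each of these genes had a limma adjusted p of 1.00 after rounding.

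By limma, 0 of 16591 genes passed an adjusted p of 0.05, with 155 below 0.05 before adjustment. By edgeR 0 passed (134 before adjustment), and by DESeq2 55 passed, 3 higher and 52 lower. DESeq2's lower genes included Ltf, Cd177, Ngp and Camp, and its higher ones Tbx1 and Golga7b. In simulated data of the same size the limma test recovered 88% of genes changed 4-fold and 10% of those changed 2-fold. That simulation held no change of the C-PC effect with stage. The real differences had opposite signs at the middle and late stages for most genes, so these shares do not carry over to the data.

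As a set, the neutrophil list lay lower with C-PC in each stage, with medians over the tested members of -0.61, -4.77 and -1.71, and 17 of 18 members had a negative pooled difference. Markers of marrow, bone and cartilage, in lists written after the values were seen, were lower with it. Granulocyte precursor genes had medians of -7.33, -4.67 and -4.73 at the early, middle and late stages. In the same order erythroid precursor genes had -3.86, -4.15 and -3.17, cartilage genes -3.52, -1.17 and -5.12, and bone genes -3.89, -3.27 and -1.69. Mature neutrophil genes had -0.15 (1 of 12 lower), -5.57 (12 of 12) and -0.37 (5 lower and 3 higher). In the neutrophil list 5 members passed when adjusted over the list alone, and 0 when adjusted over all genes. Pooled medians were -1.76 for T and NK cells, -2.09 for B and plasma cells, -1.17 for erythrocytes, -2.14 for antimicrobial genes, -0.47 for growth factors and -0.22 for the TGF-beta pathway. Over the tested members these lists kept 1 sign in each stage, as did the sebaceous gland list (0.20), which did not pass, except that the late TGF-beta median was 0.00 after rounding and 0.55 under scaling by total reads. Over all members compared at the late stage, T and NK cells (0.22) and antimicrobial genes (0.83) were positive. By limma's camera with a preset correlation, 20 of 37 lists passed an adjusted p of 0.05. With an estimated correlation 0 passed, the adjusted p lying between 0.639 and 0.922. Only 2 residual degrees of freedom remain, so the list calls rest on the preset correlation. The other passing lists had pooled medians of 3.03 (hair follicle), 2.33 (melanocytes), 0.66 (Schwann cells), 0.54 (myogenic regeneration) and 0.40 (Wnt pathway) on the higher side. On the lower side they had -1.57 (cytokines), -1.09 (skeletal muscle), -0.93 (matrix), -0.91 (interferon-stimulated genes), -0.90 (proteases), -0.65 (macrophages), -0.60 (endothelium) and -0.52 (angiogenic factors). Leaving out the middle or late pair turned the sign of 11 of the 20.

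Stages were compared with the treatment as a covariate, on recovered reads scaled together, since the deposited tables were scaled separately. Between the early and late stages, Prg4, the lubricin of joints and tendons, differed by -6.95 (SE 0.83), Thbs4, a tendon matrix protein, by -4.77 (SE 0.60), Chil3, a macrophage chitinase-like gene, by -5.51 (SE 0.81), Abi3bp by -2.73 (SE 0.44) and Ifit1, an interferon-stimulated gene, by -4.85 (SE 0.78). Higher in the late libraries were Aldh3b2 at 5.10 (SE 0.68), Golga7b at 6.23 (SE 0.94), Elovl6, a fatty acid elongase, at 3.46 (SE 0.53), Tenm4 at 3.49 (SE 0.59) and Wnt4, a secreted signal, at 4.81 (SE 0.82). These 10 had a limma adjusted p of 0.772 and did not pass, while each of them passed by DESeq2. Interferon-stimulated genes had a median of -3.77, with 16 of 20 members passing when adjusted over the list alone, and neutrophil genes -4.67, with 13 of 18. No member of either list passed when adjusted over all genes. Each stage held 2 libraries, which at the middle and late stages differed as described.

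Between the early and late stages 0 of 16591 genes passed by limma (1066 before adjustment), 0 by edgeR (917) and 661 by DESeq2, 235 higher and 426 lower. Camera gave 21 of 37 lists with a preset correlation and 0 with an estimated one (adjusted p 0.716 to 0.957). Besides the neutrophil and interferon lists, the passing lists lower at the late stage were cytokines (-5.54), macrophages (-3.61), proteases (-3.12), matrix (-2.78), antimicrobial genes (-2.10), alternatively activated macrophages (-2.08), proliferation (-1.95), myogenic regeneration (-1.70), angiogenic factors (-0.90) and the TGF-beta pathway (-0.43). Those higher were hair follicle (5.48), epidermal differentiation (4.21), basal keratinocytes (4.04), sebaceous gland (3.25), adipocytes (3.08), Schwann cells (1.71), mitochondrially encoded genes (1.32), oxidative phosphorylation (1.26) and the Wnt pathway (0.83). Several of these differences were not common to both treatments. From early to late the summed hair follicle level went from 5.55 to 1.61 CPM in the controls and from 4.99 to 61947 with C-PC, epidermal differentiation from 83.0 to 7.29 and from 114 to 4146, and basal keratinocytes from 563 to 552 and from 489 to 7444. The Wnt pathway went from 1283 to 447 CPM in the controls and from 1563 to 2066 with C-PC, proliferation from 1772 to 116 and from 1677 to 1909, and Schwann cells from 397 to 937 and from 525 to 398. Between the early and middle stages Hcar2, a niacin receptor gene, gave -3.97 (SE 0.80), Myh3, the embryonic myosin, -3.94 (SE 0.81), Prg4 -3.98 (SE 0.83), Olfr56 -4.11 (SE 0.91) and Ifit2 -2.90 (SE 0.64). Cyp4f39 gave 5.14 (SE 1.08), Cst6, a protease inhibitor of epidermis, 3.90 (SE 0.91), Slc25a48 3.81 (SE 0.92), Car1 3.71 (SE 0.83) and Has3, a hyaluronan synthase, 3.48 (SE 0.79). The limma adjusted p of these 10 was 0.988, and 0 genes passed (168 before adjustment), against 0 by edgeR (119) and 19 by DESeq2, among them Hcar2, Myh3, Prg4 and Cyp4f39. Between the middle and late stages the clock genes Per2 and Per3 gave -2.69 (SE 0.48) and -2.35 (SE 0.51), the tendon genes Thbs4 and Tnmd -2.89 (SE 0.60) and -2.05 (SE 0.44) and Angptl1 -2.06 (SE 0.44). Hmgcs1 and Nsdhl, enzymes of cholesterol synthesis, gave 1.76 (SE 0.42) and 1.67 (SE 0.46), Golga7b 3.77 (SE 0.94) and Dnah7c 3.43 (SE 0.98). Here too 0 genes passed by limma (145 before adjustment) and by edgeR (141), and 9 by DESeq2, among them Golga7b.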

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

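All tests of explanations in this part were chosen after the results had been seen. The first pattern is that the middle C-PC library resembled the late control (Spearman 0.980) and differed from its own control; an exchange of labels between the middle and late C-PC libraries goes with the late C-PC library's correlation of 0.748 with the middle control against 0.658 with its own. The difference of the mean of Per1 to Per3 from Arntl goes the other way without settling it: the middle C-PC library lay 0.88 from the middle control and 3.01 from the late control, and the late C-PC library 0.55 from the late control and 3.34 from the middle control, yet the middle C-PC value (1.55) was nearest those of the early libraries (1.47 and 1.41). Per2 and Per3 were among the genes with the smallest limma p-values between the middle and late stages. That ranking favours genes alike within a stage, so their pairing by stage is partly given by it. Other clock genes were looked at first, and Nr1d1, Dbp and Tef did not pair by stage. With no time of day given, the exchange cannot be told apart from a difference in tissue. Even dilution of wound tissue by muscle and fat was tested without a decision. The matrix median lay 2.95 above that of wound-edge keratinocytes. This was more than the middle-half spread of the first list (1.39) and less than that of the second (4.58). That test depended on the genes, as the 4 keratinocyte sets tried held from 0 reads of 2370 expected (6 keratins picked for their 0 reads) to 11341 of 2352 (basal list). Between them lay the epidermal differentiation list, fixed in advance, with 117 of 1559, and the wound-edge list with 1135 of 1855. Expected reads take the share kept by the matrix list (5.45%), and both of these lists held fewer while the basal list held more. An endothelial comparison was dropped because muscle holds endothelium, and muscle and fat make matrix too.

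The second pattern is the higher level of hair follicle genes in the late C-PC library. Hair follicle reads per basal keratinocyte read stood 231-fold above the middle control (8.32 against 0.036). This argues against more epidermis in that control's proportions as the whole cause. The ratio is built from the genes of the pattern, so it does not test more skin that holds follicles. Epidermal differentiation genes were higher as well, at 4146 CPM against 7.29 in the late control. Sharing of reads between keratin paralogs as the whole cause is argued against by the 7 of 7 members outside the keratin families that were at least 2-fold higher, such as Tchh and Hoxc13. Growing, pigment-making follicles in that piece of skin are a candidate explanation that was not decided. In 10 of 10 melanocyte genes the level was higher, but the late control held few skin transcripts, so more skin alone could give this. The melanocyte list summed to 1697 CPM, against 42.0 in the middle control, which held epidermal differentiation genes at 1665 CPM. Hair cycle, biopsy site, body region and C-PC stay open alike, since 1 library per group confounds them.

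The third pattern is the lower level of marrow, bone and cartilage genes in the early C-PC library, tested with marker lists written after the values were displayed. A surplus of mature neutrophils in the control was tested by the medians of mature neutrophil genes (-0.15) and granulocyte precursor genes (-7.33), which differed by 7.18. Of these lists 10 of 12 and 3 of 12 genes are also in the lists fixed before. Genes were sorted into them after their values were seen, so the gap restates the pattern and decides nothing. The values show only that 1 of 12 mature neutrophil genes was at least 2-fold lower. The neutrophil list fixed before had a median of -0.61, with 7 of 18 members lower. A piece of cartilage, bone and marrow in the control tissue cannot be told apart from an effect of C-PC, because the bone (-3.89), erythroid precursor (-3.86) and cartilage (-3.52) lists were written from the values that make up the pattern, and their medians restate it. The pattern is not confined to the early stage, as granulocyte precursors were lower at the middle (-4.67) and late (-4.73) stages and cartilage at the late stage (-5.12, 10 of 10). It was weaker for cartilage at the middle stage (-1.17, 6 of 10 lower). Bone genes had -3.27 at the middle stage (6 of 8 lower, 1 higher) and -1.69 at the late stage (3 of 6 lower, 19.3 CPM against 30.3). At the middle stage mature neutrophil genes (-5.57) lay below precursor genes, the reverse of the early order. At the early stage granulocyte precursors summed to 2077 CPM in the control and 15.0 with C-PC, led by Ngp at 866 and 5.64 CPM.

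Another 18 results were picked out because a list's median lay outside the random range on opposite sides at different stages. The differences between stages were not tested. Where the middle and late stages are set against each other, the differences largely restate the first pattern. The nearly alike middle C-PC library and late control lie on opposite sides of these ratios. The late median exceeded the middle one by 16.36 for hair follicle genes, 14.36 for epidermal differentiation, 13.70 for wound-edge keratinocytes, 11.06 for basal keratinocytes and 8.02 for proliferation. It exceeded it by 4.82 for the Wnt pathway, 4.57 for granulation tissue matrix, 4.40 for macrophages and 2.38 for immediate early genes. The middle median exceeded the late one by 11.37 for skeletal muscle, 6.71 for myogenic regeneration, 6.35 for adipocytes, 4.32 for oxidative phosphorylation, 3.93 for mitochondrially encoded genes, 2.69 for Schwann cells and 2.56 for glycolysis. The early median exceeded the middle one by 2.45 for interferon-stimulated genes and 1.83 for myofibroblasts.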

How the results depend on the processing

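edgeR's test, other pseudocounts in the fits and genes missing from a table set to 0, and total reads for lists, were chosen after seeing the data. Counts of genes and lists and the stage correlations stayed within limits in 90 of 103 recomputed values, and the cause was not tested for the other 13 except where a stricter rule leaves fewer genes. DESeq2 called 55 genes for C-PC over the stages, 19 for middle against early, 661 for late against early and 9 for late against middle, against 0 by limma in each. The early count of 1622 became 545 at 4-fold, 525 at 100 reads or more and 558 with the authors' adjusted p; 4-fold gave 4782 at the middle and 4391 at the late stage. The early to middle correlation of -0.022 became -0.134 (Spearman) and -0.157 (mean of 10 CPM or more). With an estimated correlation camera passed 0 lists in both comparisons. The early wound-edge keratinocyte median became -0.021 at a mean of 5 CPM or more, and of the other recomputed list medians within a stage 319 stayed within limits and 7 moved. For the named genes, 369 recomputed values kept direction and call or moved little, 49 moved and 22 passed by DESeq2 only, and the cause was not tested.

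Leaving out each stage in turn gave 0 called genes (43 to 383 before adjustment, without the early and the middle stage), 19 to 26 passing lists, and a turned sign for 11 pooled list medians: Schwann cells -0.092 to 1.56, matrix -1.82 to 0.48, cytokines -3.09 to 0.70, macrophages -1.57 to 0.55, proteases -2.32 to 0.29 and myogenic regeneration -1.59 to 1.65, turned without the middle stage; Wnt -0.93 to 1.57, endothelium -0.97 to 0.18, hair follicle -1.73 to 6.01, melanocytes -0.57 to 4.20 and muscle -3.88 to 1.65, turned without the late stage. Leaving out each library gave 0 called genes between stages, while the genes below 0.05 before adjustment ran from 10 (without the early C-PC library) to 3304 (without the middle control) for middle against early, from 36 (without the early C-PC library) to 2181 (without the middle control) for late against early, and from 20 (without the early control) to 1452 (without the middle C-PC library) for late against middle; where this left a stage with 1 library, that library is taken to vary like the others. No paired analysis beyond the stage block was possible because the labels carry no replicate numbers. All 10 splits of the 6 libraries into 3 and 3 gave 0 called genes, the real split and the highest other alike. With the stage block kept, some splits part the libraries of only 1 stage. Their difference rests on that pair, so they are not comparable with the real split. In any case 10 splits are too few for a share under 0.05. Among splits that parted all 3 stages, those with the middle C-PC library and the late control on the same side held 2086 and 1082 genes below 0.05 before adjustment by limma. Those that set them on opposite sides held 155 (the real split) and 41. The gap thus largely restates the likeness of the middle C-PC library and the late control. Depth limits genes near the 3-read floor.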

Other observations

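The genes given here were chosen after their values were seen, and they stand for no group of genes. Prg4, the lubricin of joint and tendon surfaces, stood at 1703 CPM in the early control, 355 in the early C-PC library and 43.6 or less in each of the other libraries. Comp, a cartilage and tendon matrix protein, stood at 157 CPM in the early control and 17.3 with C-PC, and at 33.1 in the late control and 1.29 with C-PC. Fmod, a collagen-binding proteoglycan, stood at 293 and 66.6 CPM in the early control and C-PC libraries, 156 and 354 in the middle ones and 131 and 11.4 in the late ones. The slow muscle genes Myh7 and Myl2 were almost absent from the early and late C-PC libraries (0.178 and 0.059 CPM for Myh7, 0.356 and 0 for Myl2). In the other 4 libraries Myh7 stood between 80.4 and 135 CPM. Fast Myh4 at the early stage stood at 1105 CPM with C-PC and 2496 in the control.

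Scd1, the stearoyl-CoA desaturase, stood at 7443 CPM in the middle C-PC library and 20205 in the late control, against 280 in the middle control and 1409 in the late C-PC library. Fasn, the fatty acid synthase, stood at 2793 and 5721 CPM in the first pair and 136 and 674 in the second. The clock gene Nr1d1 stood at 268 CPM in the late control and between 22.8 and 53.6 in the other 5 libraries.

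Some genes with near-identical copies differed between libraries without following treatment or stage. Gapdh stood at 10, 101, 5.11, 41.8, 310 and 2.05 CPM in the early control, early C-PC, middle control, middle C-PC, late control and late C-PC libraries. In the same order Cwc22 stood at 30.7, 138, 68.3, 10.3, 40 and 136 CPM, and Rps2 at 371, 6.59, 328, 191, 482 and 1032 CPM.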
